A study of Homo sapiens with 6 samples.

How the data were processed

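The series holds RNA sequencing of frozen tumour tissue from 3 patients, each sampled before and after treatment, 6 libraries in all. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a low-input SureSelect reagent kit, a chemistry usually paired with capture probes. Whether probes were used, the strand setting of the counting, the handling of duplicate reads and the site and type of each specimen are not given in the sources used here. Reads were aligned with STAR and counted with HTSeq 0.11.0 on hg19, per the submitters' processing notes.

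For each library the authors deposited whole-number counts per gene with RPKM values beside them, and counts per exon in a separate table. The RPKM values are, per the file headers and the values, counts per kilobase scaled to the total of all counts in the table, rows given to no gene included. The gene counts were used for every test, and RPKM was used only to check that the denominator equalled the total of all counts. In the deposited exon counts 82.5% to 85.6% of the reads stood in the ambiguous row, so they were not tested. The rows that name no gene held 9.80% to 12.4% of the counts per library (ambiguous 5.78% to 7.79%, not unique 3.08% to 4.11%, no feature 0.20% to 0.55%), and they were left out of library sizes and tests. The gene table also lists 99 rows of viral genes, which had 0 counts in all libraries. An identifier listed on more than 1 row of the gene table was counted once. Rows of chromosome Y, XIST and TSIX were removed before any test, which left 57276 genes. Because the strand setting is not known, reads of overlapping genes or antisense partners cannot be told apart where the counting did not use strand.

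Counts assigned to genes totalled 166954345 to 215785721 per library before those rows were removed. The depth makes counting error small beside the differences between libraries. No molecular identifiers are described, so counts are reads and not molecules.

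Gene types came from GENCODE release 29 by Ensembl identifier, which matched 52338 of 57773 human genes. That annotation is on GRCh38, so no coordinate was taken from it, and the positions in the text are those of the authors' tables (hg19).

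Pre- and post-treatment libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, library sizes were scaled with TMM, and a quasi-likelihood model with the patient as a block and treatment as the tested term was fitted, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the absolute change divided by the square root of the F statistic. The pairing comes from the labels, which give the same patient for both libraries of a pair. The deviations of the libraries of a pair from their group means correlated across genes at -0.23, -0.12 and 0.28. Between pre- and post-treatment libraries of different patients these correlations ran from -0.40 to 0.43. Expression therefore does not show the pairing, which rests on the labels alone. The common dispersion was 0.52, a biological coefficient of variation of 0.72, with 2 residual degrees of freedom and a prior of 2.32. Log2 CPM values used a prior count of 2. The 3 pairs are separate patients, so the p-values of single genes measure the spread between these patients. List p-values with the preset correlation set the genes of a list against other genes and do not measure that spread.

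A total of 44 gene lists (pathways, signs of RNA quality and cell types the tissue could hold) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. The estimated setting and fry also rest on the 2 residual degrees of freedom of the fit, so a lost call need not come from correlation. For the hepatocyte list, with an estimated correlation of -0.015, the unadjusted camera p still went from 2.00e-13 to 0.0163. All 44 had enough members. For each pair, the median of a list was set beside 10000 random lists of the same size, matched on mean expression in 20 bins. The genes named in the text are 12 fixed genes of the oestrogen receptor and cell cycle axis, the 10 protein-coding genes per direction with the largest change among those past the threshold with the same sign in 3 of 3 pairs and a mean log2 CPM of at least 1, with places not filled taken by the smallest p, and up to 4 members of each called list, and of the replication, mitosis and oestrogen receptor target lists in any case, by smallest p in the direction of the list test. Immunoglobulin and T cell receptor segments, HLA-DRB and HLA-DQ genes and genes with common whole-gene deletions were never named. Other HLA genes could be, and reads of variable ones may align less well in some libraries. A gene that the rule takes is not reported here, which leaves 9 named genes that were higher.

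The fit was tested on simulated counts drawn from the real means and library sizes of the post-treatment against pre-treatment comparison. At the fitted dispersions 0 of 67 genes changed 2-fold, 0 of 67 changed 4-fold and 0 of 66 changed 16-fold were called among 19084 genes, although 92.5%, 98.5% and 100% had the right sign. At a dispersion of 0.05, with 19403 genes, 43 of 66, 65 of 65 and 66 of 66 were called, with 11 calls among 19184 unchanged genes. In both simulations camera with the preset correlation called the immediate early list, which was raised by 2 on the log2 scale, and 0 of the 43 other lists. The estimated correlation and fry were not tried on simulated counts. Simulated genes were drawn independently of each other, so this says little about false calls of lists whose genes move together. In the real data the estimated correlation was 0.96 for the tumour epithelium markers.

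The alternatives were the fit with no replicate block, DESeq2 size factors, library sizes alone, no filter on low counts, a filter of 1 CPM in at least 3 libraries, a DESeq2 1.42.0 Wald test, limma-voom, each pair left out in turn, and the mean of the tumour epithelium markers as a covariate. For lists, members shared between lists were also left out. Limma-voom with sample quality weights was added after the data were seen. The covariate fit and the fits without a pair leave fewer residual degrees of freedom than the main fit. The covariate rests on 3 pairs, and the tumour epithelium markers changed most in pair 2. Values from that fit therefore do not show that tumour content was held constant.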

Results

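RNA was sequenced from frozen tumour tissue of 3 patients with low-grade serous carcinoma, an ovarian cancer that often carries oestrogen receptor and grows slowly. Each patient gave 1 library before and 1 library after treatment with fulvestrant, an oestrogen receptor antagonist and degrader, and abemaciclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6. The 6 libraries therefore form 3 pairs, called pairs 1, 2 and 3, with n = 3 libraries in each group. Counts assigned to genes were 166954345, 177103607 and 185719631 in the pre-treatment libraries of pairs 1, 2 and 3, and 215785721, 193559431 and 186006651 in their post-treatment libraries. Between 21111 and 22364 genes had a count in each library, and the 10 most abundant genes took 6.98% to 14.5% of the counts. At this depth counting error was small, and the spread between libraries set the precision. Group values below are means ± SD of TMM-scaled CPM, the count of a gene per 1e6 counts, and changes are post- minus pre-treatment on the log2 scale with their standard errors (SE).

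The comparison asked how expression in the tumour tissue differed after the drug combination. Several of the genes with the smallest p were immediate early genes, which are switched on within minutes by growth factor or stress signals. NR4A3, an orphan nuclear receptor (ENSG00000119508, chromosome 9, 102584137 to 102629173, hg19), averaged 9.26 ± 12.2 CPM before and 68.1 ± 83.7 CPM after treatment, a change of 3.05 (SE 0.28) that was between 2.82 and 3.23 in each pair. EGR1, a zinc finger transcription factor (ENSG00000120738, chromosome 5, 137801179 to 137805004), went from 229 ± 226 to 1350 ± 1273 CPM, and EGR2 from 14.6 ± 5.81 to 121 ± 90.7 CPM. Among the genes lower after treatment, SPEG, a muscle-type protein kinase (ENSG00000072195, chromosome 2, 220299568 to 220363009), went from 208 ± 18.8 to 57.2 ± 17.0 CPM.

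No single gene passed the test over all genes. Among 19641 genes tested, 0 were higher and 0 were lower after treatment at an adjusted p below 0.05 (edgeR quasi-likelihood test, patient as a block, Benjamini-Hochberg adjustment), and the smallest adjusted p was 0.9997. At an unadjusted p below 0.05 there were 246 higher and 137 lower genes. Limma-voom also called 0 and 0 genes, while a DESeq2 Wald test on the same counts called 98 higher and 45 lower. The paired changes had little in common across patients, since 18.5% of the genes moved in the same direction in all 3 pairs, against 25% for independent signs. The treatment term held 16.8% of the variance of log2 CPM and the patient term 40.8%, close to the 20% and 40% that their degrees of freedom give with no effect of either.

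The 9 genes named as higher after treatment were therefore chosen by rank of p among genes that moved alike in 3 of 3 pairs, and none is past the edgeR threshold. Besides NR4A3, EGR1 and EGR2 they were SIK1, a salt-inducible kinase (change 2.84, SE 0.33), IER3 (2.43, SE 0.33), CSRNP1 (2.70, SE 0.45), KRT5, a basal epithelial keratin (2.76, SE 0.31), TPPP3, a tubulin-binding protein of ciliated cells (2.71, SE 0.40), and TBX3, a T-box transcription factor (1.55, SE 0.25). The 10 named as lower were LBP, the lipopolysaccharide-binding protein (-6.35, SE 0.59), SIX2 (-5.02, SE 1.14), PITX1 (-2.60, SE 0.56), ALPK2 (-2.50, SE 0.45), the kinase MATK (-2.46, SE 0.34), the adhesion molecules L1CAM (-2.22, SE 0.49) and VCAM1 (-1.78, SE 0.39), SPEG (-1.90, SE 0.31), COL24A1 (-1.64, SE 0.33) and the ryanodine receptor RYR1 (-1.49, SE 0.32). DESeq2 called all 9 of these higher genes, and among the lower ones it did not call VCAM1 or RYR1. The genes were ranked by p on the same counts, so these calls are no independent support. In another split of the libraries that parts all 3 pairs DESeq2 called up to 970 genes, against 143 in the real one. LBP was near 0 in both libraries of pair 3, so its change rests on pairs 1 and 2.

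**Figure D1:**
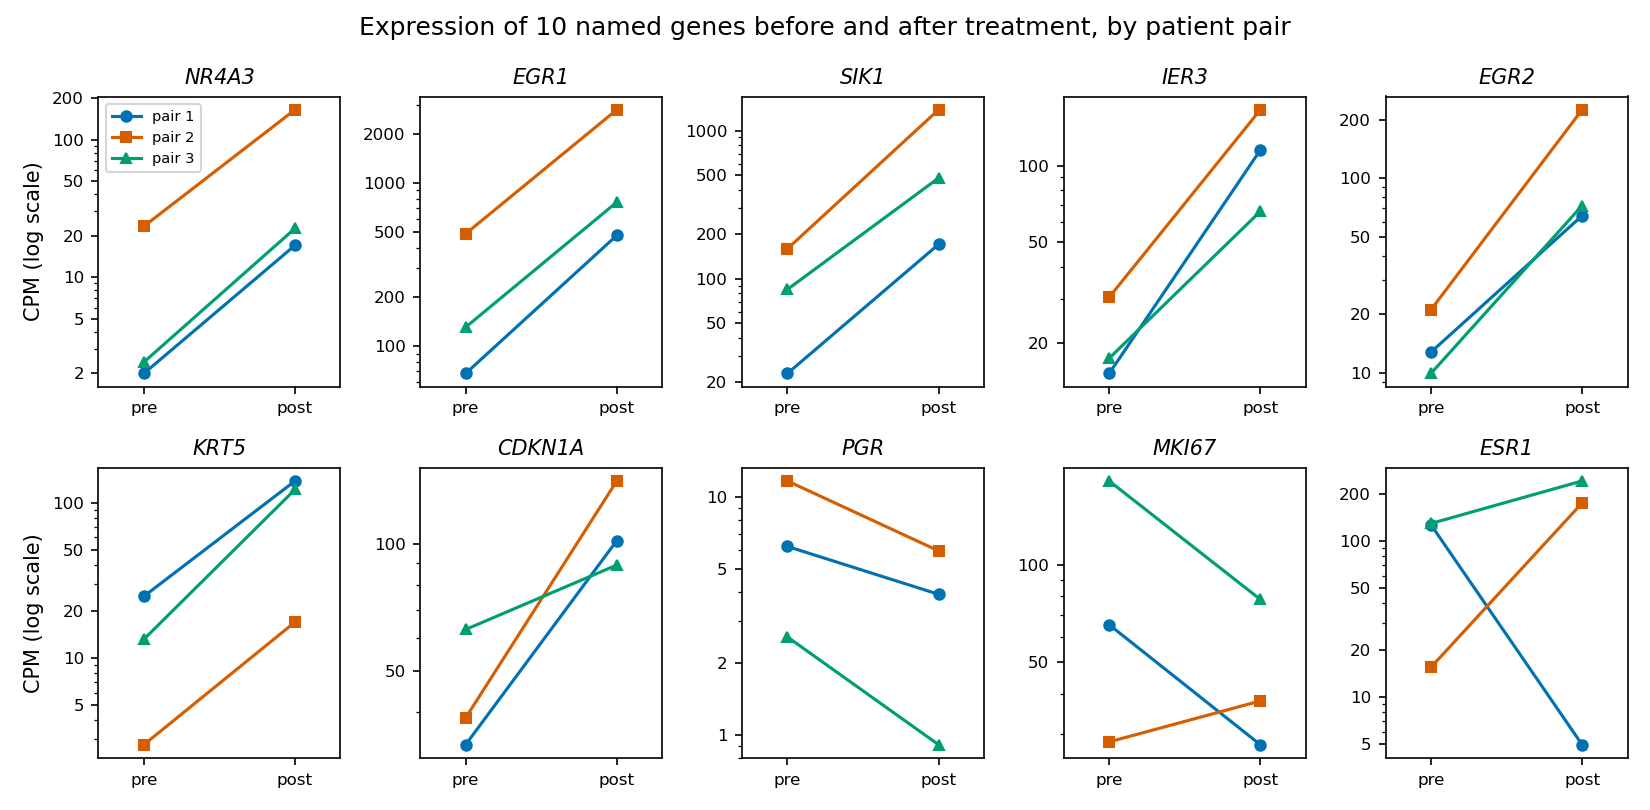
TMM-scaled CPM (log scale) of 10 named genes in the pre- and post-treatment library of each patient, with 1 line per pair and no averaging. NR4A3, EGR1, EGR2, SIK1, IER3, KRT5 and CDKN1A were higher after treatment in 3 of 3 pairs and PGR was lower in 3 of 3, while MKI67 and ESR1 moved in different directions.

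The immediate early genes rose as a group. All 22 tested members had a positive change, 20 of them in every pair, and the median change was 2.32, with medians of 1.71, 2.49 and 2.85 in pairs 1, 2 and 3. Of the 22 genes, 15 passed when adjusted over the list alone and 0 when adjusted over all genes. The list stood apart from other genes with the preset correlation of 0.01 (camera, adjusted p = 3.38e-47). It was not called in the setting with an estimated correlation, which was 0.22 for this list (adjusted p = 0.455 with an estimated correlation). Markers of tumour epithelium did not move with it: their median change was -2.19 in pair 1, 5.74 in pair 2 and 0.59 in pair 3. Heat shock and chaperone genes had a median change of -0.046 and a mean of 0.048, with 7 of 16 members higher, and were not called (adjusted p = 0.79).

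Genes of the senescence-associated secretory programme, which are cytokines, chemokines and matrix enzymes released by arrested or inflamed cells, also rose as a group. Of 22 tested members 21 were higher, with a median change of 2.72 and pair medians of 3.33, 0.82 and 1.46. CCL20, a chemokine, went from 0.91 ± 0.66 to 7.48 ± 3.93 CPM. The call (adjusted p = 8.92e-18) was not kept with an estimated correlation (adjusted p = 0.71 with an estimated correlation), and the median was 1.64 without pair 1, in which neutrophil markers were higher by 3.52. MAPK pathway output genes, which follow the activity of the RAS-ERK cascade, had 13 of 14 members higher and a median change of 0.68 (adjusted p = 5.94e-06, and adjusted p = 0.71 with an estimated correlation). DUSP5, a phosphatase of ERK, went from 11.5 ± 2.23 to 130 ± 131 CPM and PHLDA1 from 33.5 ± 14.6 to 105 ± 29.3 CPM. The MAPK median was 2.07 in pair 2, where tumour epithelium markers were higher by 5.74, and without that pair the median was -0.011 and the list was not called. With the tumour epithelium score as a covariate it was 0.38.

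Because fulvestrant acts on the oestrogen receptor, its gene and its targets were examined directly. ESR1, which encodes the receptor (ENSG00000091831, chromosome 6, 151977826 to 152450754), was at 90.5 ± 65.0 CPM before and 141 ± 122 CPM after treatment, a change of 0.44 (SE 2.11). In the separate pairs ESR1 changed by -4.68, 3.49 and 0.91, and tumour epithelium markers by -2.19, 5.74 and 0.59. PGR, the progesterone receptor and a direct target (ENSG00000082175, chromosome 11, 100900355 to 101001255), was at 6.84 ± 4.60 CPM before and 3.59 ± 2.54 CPM after, lower in 3 of 3 pairs with a change of -1.05 (SE 0.43). PGR was highest, at 11.7 CPM, in the pre-treatment library of pair 2, where tumour epithelium markers were lowest. GREB1, another direct target, changed by -0.16 (SE 0.80) and moved down in 2 pairs and up in pair 2. Of 34 tested oestrogen receptor targets 18 were higher and 16 lower, the median change was 0.0092, and the list was not called (adjusted p = 0.583). The medians within pairs 1, 2 and 3 were 0.11, 0.33 and 0.086, each inside the range of random lists. The members with the smallest p in the direction of the list test were EGR3 (change 2.83, SE 0.55), which is also an immediate early gene, RARA (0.71, SE 0.30), AREG, the growth factor amphiregulin (2.89, SE 1.61, at 0.11 ± 0.15 CPM before and 0.53 ± 0.54 CPM after), and PDZK1 (1.07, SE 0.69). This rule passes over the members that fell. In 3 of 3 pairs 5 members were higher and 3 were lower, PGR among the latter, 1 in each direction had an unadjusted p below 0.05, and the lowest change was -3.45. None of the 34 passed when adjusted over the list alone, and the sign of the median turned under several settings.

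Because abemaciclib inhibits CDK4 and CDK6, which release E2F from RB, genes of the cell cycle were examined next. DNA replication and E2F target genes had 40 of 46 members lower after treatment, with a median change of -0.33, and mitosis genes had 40 of 42 lower, with a median of -0.60. Both lists fell against other genes with the preset correlation (adjusted p = 0.00127 and 8.96e-06), and neither did with an estimated correlation (adjusted p = 0.752 for each with an estimated correlation). ATAD2, a chromatin factor, changed by -1.11 (SE 0.35), the helicase BLM went from 5.53 ± 1.81 to 2.58 ± 0.32 CPM, and the replication licensing factors MCM6 and MCM5 changed by -0.52 (SE 0.25) and -0.58 (SE 0.32), all lower in 3 of 3 pairs. Among mitosis genes NUF2, a kinetochore protein, changed by -1.40 (SE 0.69) and MYBL2 by -0.59 (SE 0.33), each lower in 3 of 3 pairs, and BUB1 by -0.75 (SE 0.47) and HJURP by -0.80 (SE 0.52), each lower in 2 pairs. MKI67, the Ki-67 antigen, was at 91.8 ± 79.9 CPM before and 48.0 ± 26.6 CPM after (change -0.69, SE 0.46), and TOP2A changed by -0.41 (SE 0.70). No member of either list passed when adjusted over the list alone.

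The direction of these 2 lists differed between patients. The replication median was -0.71, 0.84 and -1.08 in pairs 1, 2 and 3, and the mitosis median -1.38, 0.69 and -0.99, while tumour epithelium markers moved by -2.19, 5.74 and 0.59. The fitted replication median was -0.90 without pair 2, -0.11 without pair 1 and 0.0077 without pair 3, and the mitosis median was -1.25, -0.16 and -0.28 in the same order. Neither list was called without pair 1 or without pair 3. With no block for the pairing the medians were -0.52 and -0.80, and with the tumour epithelium score as a covariate they were -0.53 and -0.81.

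Of the kinases, cyclins and inhibitors around RB, CDKN1A, which encodes the inhibitor p21 (ENSG00000124762, chromosome 6, 36644305 to 36655116), was at 45.0 ± 15.6 CPM before and 111 ± 27.0 CPM after treatment, a change of 1.33 (SE 0.38) with the same sign in 3 of 3 pairs. It did not pass over all genes, and the 20 genes of the cyclin D, CDK4/6 and RB list had 14 members higher, a median change of 0.19 and no call (adjusted p = 0.228). CDK4 changed by 0.19 (SE 0.34), CDK6 by 0.51 (SE 0.33), RB1 by 0.19 (SE 0.32), CCND1 by 0.68 (SE 0.66), CCNE1 by 0.32 (SE 0.79) and CDKN2A by 0.66 (SE 1.43), and each of these except CDK6 had pairs of both signs. p53 target genes, which include CDKN1A, had 18 of 24 members higher and a median change of 0.20 (adjusted p = 0.0121, and adjusted p = 0.752 with an estimated correlation). GDF15, a stress cytokine, went from 5.15 ± 4.52 to 49.7 ± 43.3 CPM. The p53 median was -0.098 without pair 2, 0.12 with the tumour epithelium score as a covariate and 0.17 without members shared with another list, and the list was called in none of these. With no composition scaling it was 0.12 and still called.

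**Figure D2:**
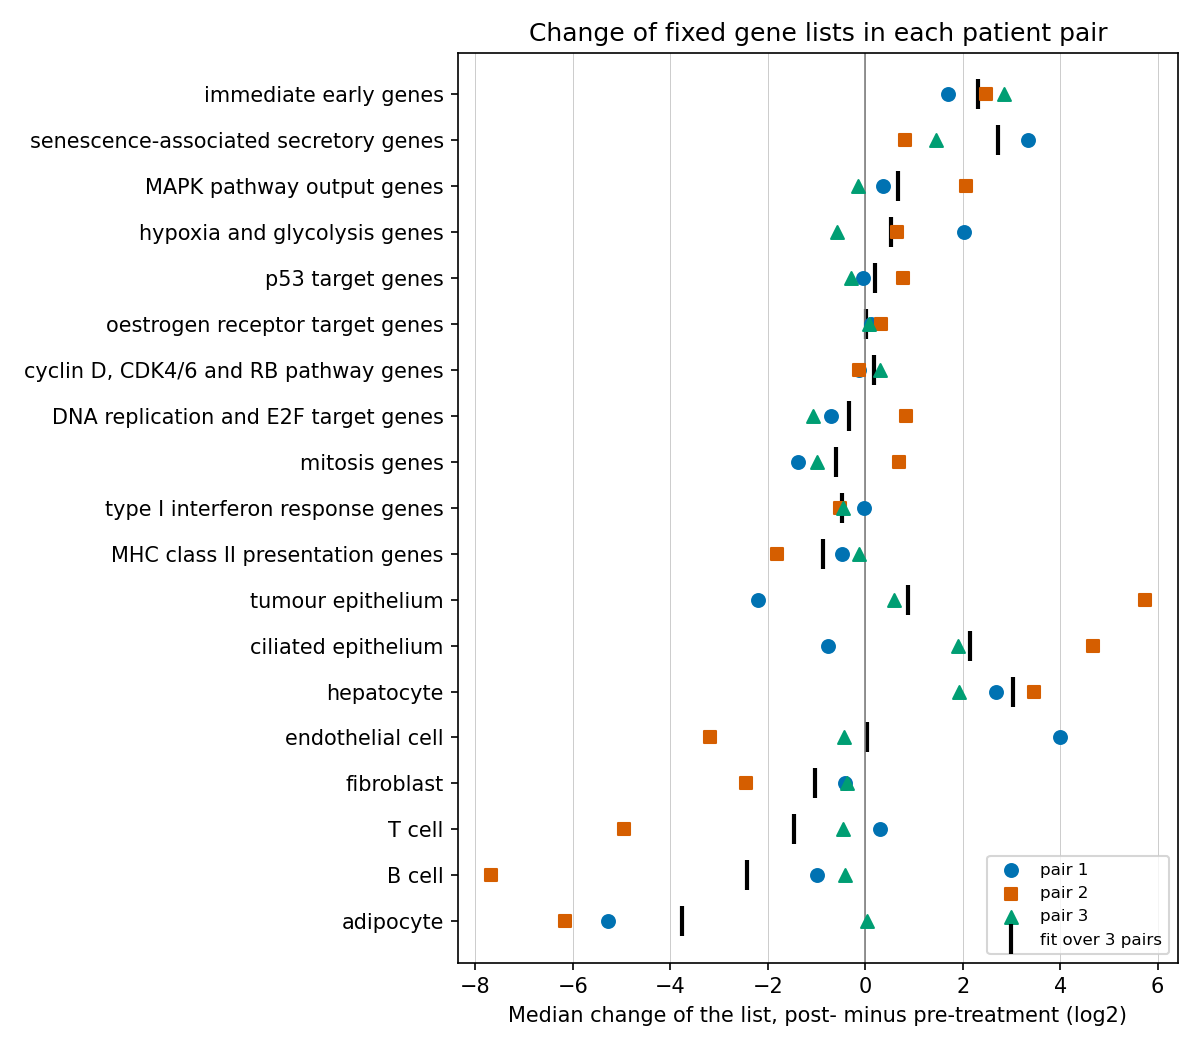
Median change of the tested members of 19 gene lists (post- minus pre-treatment, log2), with 1 coloured symbol per patient pair and a black bar for the median of the fitted changes over the 3 pairs. Immediate early, secretory and hepatocyte lists lie above 0 in every pair, and so do oestrogen receptor targets, by 0.33 or less. Tumour epithelium runs from -2.19 to 5.74, and the mitosis list lies above 0 in pair 2 alone.

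Type I interferon response and antigen presentation genes were lower as groups in the fit over the 3 pairs, though not in every pair. Type I interferon response genes had 26 of 29 members lower and a median change of -0.47 (adjusted p = 4.87e-05, and adjusted p = 0.71 with an estimated correlation), and a median of -0.24 without pair 3. The pair medians were -0.018, -0.51 and -0.46, and in pair 1, 14 of the 29 members were higher. OAS1 was at 16.8 ± 2.03 CPM before and 8.69 ± 2.96 CPM after and DDX58, the RIG-I sensor, at 32.7 ± 2.64 and 19.5 ± 7.14 CPM. MHC class II genes were lower in 10 of 10 members, with a median of -0.86 (adjusted p = 8.96e-06, and adjusted p = 0.71 with an estimated correlation). HLA-DPA1 changed by -1.04 (SE 0.44) and HLA-DPB1 by -0.91 (SE 0.40), and the class II median was -0.34, and not called, without pair 2. MHC class I presentation genes had a negative fitted change in 14 of 14 members, with a median of -0.35 (adjusted p = 0.00912, and adjusted p = 0.752 with an estimated correlation), and PSMB8, an immunoproteasome subunit, changed by -0.41 (SE 0.24). The class I pair medians were 0.46, -1.53 and -0.32. In pair 1, 10 of the 14 members were higher, and 2 members were lower in all 3 pairs. With no block for the pairing the class I median was -0.19. The class I list was not called with the tumour epithelium score as a covariate (median -0.18) or without pair 2 (0.098), in which the T cell, B cell and dendritic cell markers changed by -4.95, -7.68 and -4.34. Interferon gamma and T cell chemokine genes had a median of -0.40 and were not called (adjusted p = 0.16), but were called lower without pair 1 (-1.16). Their pair medians were 1.07, -1.65 and -0.63, beside 1.27, -1.80 and -0.54 for macrophage and monocyte markers.

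Hypoxia and glycolysis genes had 21 of 22 members higher with a median of 0.52, and pair medians of 2.03, 0.65 and -0.57 (adjusted p = 8.76e-05, and adjusted p = 0.745 with an estimated correlation). The hypoxia median was 0.048, and not called, without pair 1, 1.31 without pair 3, 0.80 with no block and 0.85 with the tumour epithelium covariate. SLC2A3, a glucose transporter, changed by 1.56 (SE 0.86) and ANKRD37 by 1.53 (SE 0.88). TGF-beta response genes had 13 of 20 members higher and a median of 0.32 (adjusted p = 0.0121, and adjusted p = 0.71 with an estimated correlation), and CTGF, a matricellular protein, went from 235 ± 166 to 1253 ± 783 CPM. CTGF is also in the immediate early list, and it changed by 0.34, 4.29 and 2.70 in pairs 1, 2 and 3. The TGF-beta list was not called without pair 3 (median 0.50) or without members shared with another list (0.20), and its median was 0.15 without pair 2. Lysosome and autophagy genes had 25 of 28 members higher and a median of 0.22 (adjusted p = 0.00739, and adjusted p = 0.721 with an estimated correlation), among them ATP6V0D1, a subunit of the proton pump, at 69.6 ± 2.88 CPM before and 98.0 ± 2.53 CPM after, and cathepsin B, CTSB, with a change of 0.69 (SE 0.37). The lysosome list was not called without pair 1 (median 0.15) or without pair 3 (0.14), its median was 0.35 without pair 2 and 0.15 with no composition scaling, and its median within pair 2 was -0.12. Replication-dependent histone genes had a median of -0.42 (adjusted p = 0.00304, and adjusted p = 0.752 with an estimated correlation) that was 0.010, and not called, without pair 1 and -0.68 with the tumour epithelium covariate, and HIST2H3D, which has near-identical copies and is uncertain for that reason, changed by -1.21 (SE 0.51). The 13 mitochondrially encoded genes were all lower, with a median of -0.47 (adjusted p = 0.00989, and adjusted p = 0.71 with an estimated correlation), and MT-CYB was at 2.98 ± 0.40 and 1.97 ± 1.03 CPM. This list was not called without pair 2 (-0.52) or without pair 3 (-0.37). These transcripts made up 0.00133% to 0.00332% of the gene counts. Whether capture probes were used and covered them is not known. The call is therefore not read as a change in mitochondrial expression or RNA quality.

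Markers of cell types differed widely between the libraries. Tumour epithelium markers averaged 2.10 log2 CPM in the pre-treatment library of pair 2 and 7.32 and 7.41 in the other pre-treatment libraries, and 4.34, 7.61 and 8.16 after treatment in pairs 1, 2 and 3. Their fitted median change was 0.88 (adjusted p = 8.75e-04, and adjusted p = 0.752 with an estimated correlation), and without pair 2 it was -0.82 and the list was called lower. With the mean of these markers itself as a covariate it was 0.22 and not called. FOLR1, the folate receptor, changed by 3.13 (SE 2.91) and SLPI by 1.86 (SE 1.79). Ciliated epithelium markers had 16 of 16 members higher with a median of 2.14 and pair medians of -0.77, 4.67 and 1.90 (adjusted p = 1.66e-10, and adjusted p = 0.71 with an estimated correlation), and both TPPP3 and ROPN1L (2.58, SE 0.59) were higher in 3 of 3 pairs. The ciliated median was 0.37 without pair 2, 3.64 without pair 1 and 1.39 with the tumour epithelium covariate.

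**Figure D3:**
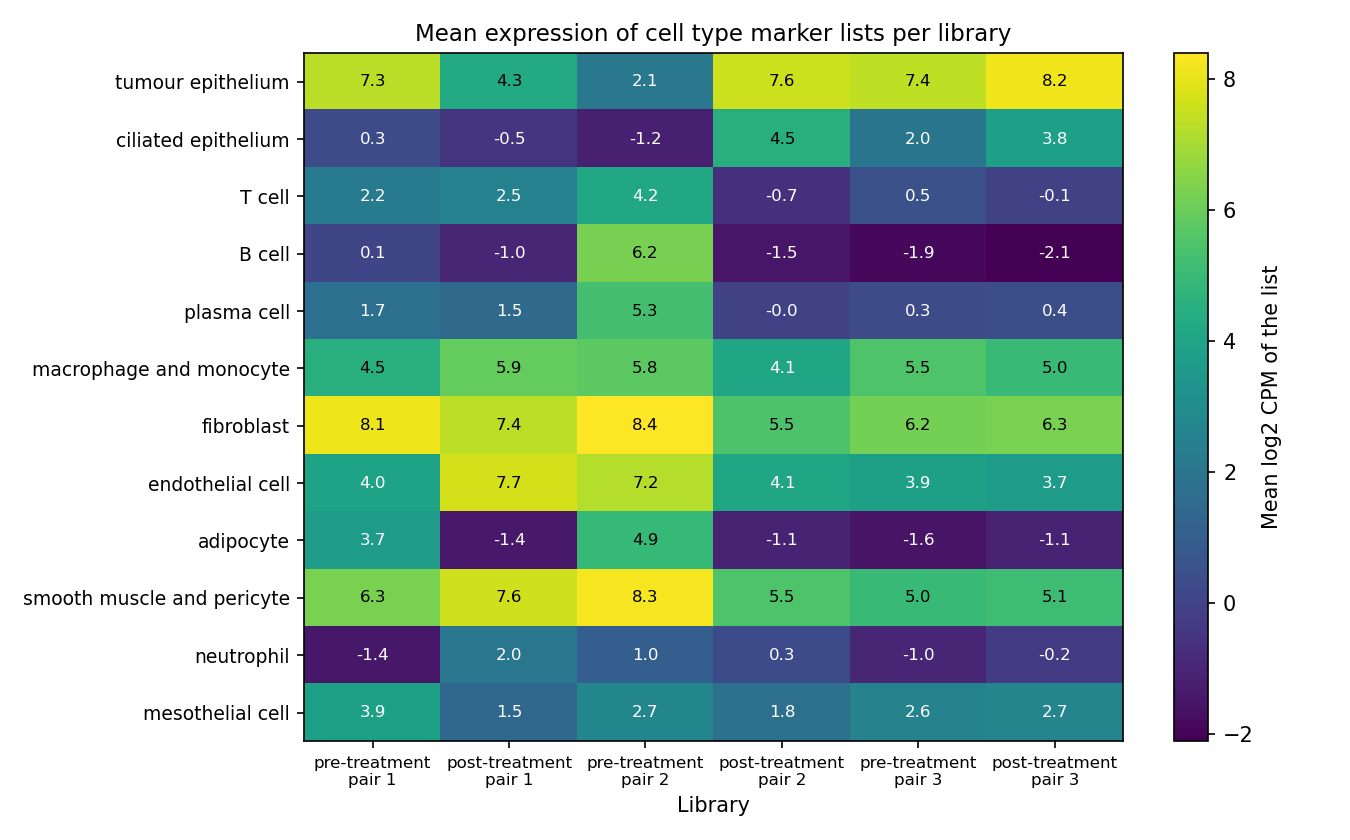
Mean log2 CPM of 12 cell type marker lists (rows) in each of the 6 libraries (columns, ordered by pair), with the value printed in each cell and the colour following it. The pre-treatment library of pair 2 had the lowest tumour epithelium mean (2.10) and the highest B cell mean (6.23).

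Lymphocyte, stromal and fat markers were lower, and for each of the 6 lists that follow the median change was largest in pair 2. B cell markers were lower in 14 of 14 members with a median of -2.43 (adjusted p = 1.51e-10), and the median was -0.93 without pair 2. CD22 went from 91.6 ± 121 to 15.3 ± 12.7 CPM and MS4A1, the CD20 antigen, from 24.1 ± 41.0 to 0.071 ± 0.064 CPM. T cell markers were lower in 18 of 18 members with a median of -1.46 (adjusted p = 5.54e-08), which was -0.12, and not called, without pair 2, and IL7R changed by -2.25 (SE 1.21). Dendritic cell markers had a median of -1.44 (adjusted p = 1.80e-06), with CLEC10A at -2.26 (SE 0.65) and XCR1 at -2.77 (SE 0.89), and plasma cell markers a median of -1.05 (adjusted p = 2.04e-04), with TXNDC5 at -1.31 (SE 0.40) and DERL3 at -2.48 (SE 0.88). Without pair 2 neither list was called, at medians of -1.05 for dendritic cells and -0.0089 for plasma cells. With no block for the pairing the B cell, plasma cell and dendritic cell medians were -5.67, -2.68 and -2.70, while the fibroblast median was smaller in size at -0.60. Fibroblast markers had 16 of 19 members lower and a median of -1.04 (adjusted p = 1.80e-06), which was -0.22, and not called, without pair 2, and among them OGN changed by -2.97 (SE 0.77) and DCN, decorin, from 853 ± 241 to 341 ± 125 CPM. Adipocyte markers had the lowest median of the 44 lists, -3.76 (adjusted p = 3.66e-12), from medians of -5.27 and -6.16 in pairs 1 and 2 and 0.043 in pair 3, and the median was -2.25 without pair 2 and -2.39 with the 1 CPM filter. PLIN4, a lipid droplet protein, changed by -3.14 (SE 1.15) and TUSC5 by -8.18 (SE 2.29). All 6 of these calls were lost with an estimated correlation (adjusted p = 0.71 for each with an estimated correlation).

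Cytotoxic lymphocyte markers had a median of -0.82 (adjusted p = 0.00625, and adjusted p = 0.752 with an estimated correlation), with EOMES at -1.97 (SE 1.08), and without pair 2 the median was 0.31 and the list was called higher. With the tumour epithelium score as a covariate the cytotoxic median was -0.39 and the list was not called. Mesothelial cell markers had a median of -1.47 (adjusted p = 0.0112, and adjusted p = 0.71 with an estimated correlation), with LRRN4 at -1.69 (SE 0.51) and PRG4 at -2.87 (SE 1.26), and the median was -0.48, and not called, without pair 1. Of the 12 members 11 were lower. The other, KRT5, was higher in 3 of 3 pairs (2.76, SE 0.31) and was the only member to pass when adjusted over the list alone. Erythroid markers had 6 of 7 members higher and a median of 2.02 (adjusted p = 1.14e-05, and adjusted p = 0.71 with an estimated correlation), with ALAS2 at 0.95 ± 0.24 CPM before and 4.86 ± 2.97 CPM after and SLC4A1 at 0.21 ± 0.10 and 1.07 ± 0.41 CPM, and the median was 0.99 without pair 3. Neutrophil markers had 10 of 13 members higher and a median of 1.07 (adjusted p = 0.00185, and adjusted p = 0.745 with an estimated correlation), from pair medians of 3.52, -1.04 and 0.62, and the list was not called without pair 1 (-0.093) or with the 1 CPM filter (0.066), and its median was 1.70 with the tumour epithelium covariate. The ovarian stroma and steroidogenic list had a median of 0.84 (adjusted p = 0.00656, and adjusted p = 0.745 with an estimated correlation), which was -0.11 without pair 2, 0.38 with the 1 CPM filter and 0.55 with the tumour epithelium score as a covariate, and the list was called in none of these. Hepatocyte markers were higher in 12 of 12 members with a median of 3.03 and pair medians of 2.69, 3.46 and 1.93 (adjusted p = 2.93e-12, and adjusted p = 0.455 with an estimated correlation). The hepatocyte median was 1.83 without pair 1, 1.86 without pair 2 and 1.07 with the 1 CPM filter, and most levels were low: FGG, a fibrinogen chain, was at 0.010 ± 0.013 CPM before and 0.86 ± 0.32 CPM after, while SERPINA1, alpha-1 antitrypsin, which other cells also make, went from 43.6 ± 8.33 to 161 ± 102 CPM.

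In total 13 lists were called higher and 15 lower of 44 with the preset correlation, and 0 and 0 were called with an estimated correlation or by fry, which tests each list alone. Both rest on 2 residual degrees of freedom and neither was tried on a simulated list, so the lost calls say little about which lists changed. Correlation alone cannot explain these losses, since the hepatocyte and TGF-beta lists had estimated correlations of -0.015 and -0.016, below the preset value. The lists not called, besides those above, were collagen and matrix genes (median -0.095), complement and coagulation genes (-0.41), cholesterol synthesis genes (0.11), oxidative phosphorylation genes (0.034), ribosomal protein genes (-0.038), and the markers of macrophages and monocytes (-0.40), mast cells (-0.43), smooth muscle and pericytes (-0.32), endothelial cells (0.028), nerve and Schwann cells (-1.55), skeletal muscle (0.22) and intestinal epithelium (0.24). For skeletal muscle and intestinal epithelium the list test pointed down although the median was above 0. Several of these lists were called under an alternative. Complement genes were called lower with no block (-0.41), without shared members (-0.51) and without pair 3 (-0.98), nerve markers with no block (-2.61) and without pair 3 (-2.17), and macrophage markers with no block (-0.24) and with the 1 CPM filter (-0.43). Macrophage, mast cell and smooth muscle markers were called lower without pair 1 (-1.12, -1.72 and -1.35) and higher without pair 2 (0.38, 0.73 and 0.92), and the last 2 also lower without pair 3 (-1.95 and -0.74). Ribosomal protein genes were called higher without pair 1 (0.37) and lower without pair 2 (-0.37) or with the tumour epithelium covariate (-0.24). Endothelial markers were called lower without pair 1 (-1.69) and higher without pair 2 (1.69) or with that covariate (1.01), and oxidative phosphorylation genes higher without pair 1 (0.45). The medians of the oxidative phosphorylation and endothelial lists changed sign with no composition scaling. Endothelial markers changed by 4.00 in pair 1, -3.19 in pair 2 and -0.43 in pair 3.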

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

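One alternative, limma-voom with sample quality weights, was chosen after seeing the data. The edgeR fits called 0 higher and 0 lower genes under all edgeR settings, each pair left out included, and limma-voom did so with and without quality weights, whereas DESeq2 called 98 higher and 45 lower genes. Of the 80 named genes 28 passed in DESeq2. With the 3 pairs and the fitted dispersions, edgeR called no simulated gene even at a 16-fold change, so the 0 says little about which genes changed. With an estimated correlation, or with fry, 0 lists were higher and 0 lower, and the replication (-0.33) and mitosis (-0.60) medians were no longer past the threshold. With no replicate block 13 lists were higher and 18 lower, all 28 main calls were shared, and the medians were -0.52 (replication), -0.80 (mitosis) and -0.10 (oestrogen receptor targets). Without the block the counts past the adjusted threshold moved by less than 1.5 times, while at an unadjusted p below 0.05 there were 384 higher and 251 lower genes. The other scalings moved the median of all genes by at most -0.075.

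The oestrogen receptor target median also turned to -0.059 with no composition scaling, -0.017 with the CPM filter and -0.021 without shared members. With no block the interferon gamma list was at 0.096. With no composition scaling oxidative phosphorylation was at -0.041 and endothelial markers at -0.069, and with the CPM filter endothelial markers were at -0.011. With the tumour epithelium covariate cholesterol synthesis was at -0.052, oxidative phosphorylation at -0.16, macrophages at 0.0095, smooth muscle at 0.021, ESR1 at -1.15, CCNE1 at -0.025 and CDKN2A at -0.29. The cause was not tested.

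With 1 pair left out at a time, lists lower numbered 9 to 16 and lists higher 11 to 14. Without pair 2, which holds the library with few tumour markers, 14 were higher and 9 lower, and 16 of the 28 main calls were shared in the same direction. The ranges of medians were -0.90 to 0.0077 (replication), -1.25 to -0.16 (mitosis), -0.059 to 0.17 (oestrogen receptor targets), -0.018 to 0.22 (cyclin D and RB), -0.011 to 1.35 (MAPK), -0.11 to 0.097 (heat shock), -0.098 to 0.34 (p53), -1.16 to 0.25 (interferon gamma), -0.89 to 0.098 (MHC class I), -0.98 to 0.19 (complement), -0.15 to 0.037 (collagen), -0.37 to 0.41 (cholesterol), -0.27 to 0.45 (oxidative phosphorylation), -0.37 to 0.37 (ribosomal) and -0.76 to 0.010 (histones). Marker medians ranged from -0.82 to 3.21 (tumour epithelium), -1.89 to 0.31 (cytotoxic lymphocytes), -1.12 to 0.38 (macrophages), -0.093 to 2.20 (neutrophils), -1.95 to 0.73 (mast cells), -1.35 to 0.92 (smooth muscle), -1.69 to 1.69 (endothelium), -0.11 to 2.32 (ovarian stroma), -2.17 to 0.13 (nerve), -0.27 to -0.066 (skeletal muscle) and -0.65 to 1.01 (intestine). Gene ranges were -1.89 to 2.19 (ESR1), -1.10 to 0.50 (GREB1), -0.085 to 1.32 (CCND1), -0.070 to 0.51 (CDK4), -0.057 to 0.45 (RB1), -0.52 to 0.97 (CCNE1), -0.78 to 2.02 (CDKN2A), -1.24 to 0.13 (TOP2A) and -0.084 to 4.88 (FOLR1). Other called lists ranged from 0.048 to 1.31 (hypoxia), 0.15 to 0.50 (TGF-beta), 0.14 to 0.35 (lysosome), -2.61 to -0.12 (T cells), -2.78 to -0.0089 (plasma cells), -2.99 to -1.05 (dendritic cells) and 0.37 to 3.64 (ciliated). The immediate early median stayed between 2.13 and 2.60.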

Other observations

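All tests of the 3 patterns below were chosen after the results were seen, and the comparison with other splits of the libraries was set out before, although its limit to splits that part all pairs was set after its values were seen. The 6 libraries can be split into 3 and 3 in 10 ways, and 4 of these, the real one included, part all 3 pairs. The 6 others part 1 pair each, and in the paired fit they carry only the change of that pair, so they were not compared. With 10 or with 4 splits no share can be under 0.05. Among the splits that part all pairs, edgeR called 0 genes in the real one and at most 0 in another, in each direction (4 of 4 as many), which says nothing here, since it called 0 of 66 simulated genes even at a 16-fold change. For gene lists, 13 were higher and 15 lower in the real split, and at most 17 in 1 direction in another (4 of 4 in each case). The size of the replication median was 0.33 in the real split and at most 0.76 in another (2 of 4 as large), of the mitosis median 0.60 and 1.07 (2 of 4), and of the oestrogen receptor target median 0.0092 and 0.076 (4 of 4). DESeq2 called 143 genes in the real split and up to 970 in another (4 of 4). The reason for the larger DESeq2 count in another split was not tested.

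Immediate early genes were higher after treatment in every pair, by a median of at least 1.71, above the upper limit of random lists in each pair. A change in tumour content is argued against, since the tumour epithelium median was -2.19 in pair 1 and 5.74 in pair 2 while the list stayed at 1.71 or more. A rise in neutrophil content was not seen in pair 2, where the immediate early median was 2.49. The neutrophil median there was -1.0378, with 12 of 13 members lower, barely inside the lower limit of random lists (-1.0381). Because 8 of the 13 averaged below 1 CPM before treatment, these markers cannot decide the question, and a change in neutrophil content stays open. Surgery, specimen handling and time to freezing cannot be told apart from treatment, because no source used here gives them and each may follow the groups, and the median of 2.32 would fit any of these. A response of the tissue to the drugs stays open as an untested explanation.

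Replication and mitosis genes were lower in pairs 1 and 3 and higher in pair 2. In pair 3 a change in tumour content is argued against as the whole cause, since the mitosis median was -0.99 while tumour epithelium markers were higher by 0.59, each outside its range of random lists. In pairs 1 and 2 the mitosis list moved in the direction of the tumour markers, but by another amount, with a gap of up to 5.04, and the effect of tumour content cannot be told apart from that of treatment in 2 pairs. A lower rate of division in the treated tumours stays open, and so does a change in dividing cells of other types.

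The hepatocyte list was higher after treatment, and 31 liver transcripts, a list written after the values of several were seen, were examined by pair. In pairs 1 and 2 their medians were 2.35 and 1.65, with 25 and 26 of 31 higher, and ALB, the albumin gene and the most abundant liver transcript, changed by 4.22 and 8.36. Traces of hepatocyte RNA are a candidate source in pairs 1 and 2, where the lower median was 1.65, although ALB reached only 1013 and 2445 counts. The 31 include members of the hepatocyte list, and several values had been seen, so these medians are no independent support. Whether such RNA came with the specimen or from another library was not tested. In pair 3 the median was 0.41, with 17 of 31 higher and 14 lower, and ALB changed by 0.28 while FGA, a fibrinogen chain, changed by 3.48 and reached 30.4 times the ALB count, against 0.23 and 0.17 times in the other post-treatment libraries, which argues against hepatocyte RNA in that pair. Expression of fibrinogen by other cells of the tissue stays open and untested. None of the 31 is in another fixed list, and 8 were at 1 CPM or more in every pre-treatment library, so the tissue also expresses them.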
